A study of Homo sapiens with 52 samples.

How the data were processed

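The data were 52 libraries from primary human hepatocytes treated in collagen-coated multiwell plates and lysed 96 h after an oligonucleotide was added, per the labels' protocols. Libraries were made with a QuantSeq 3' kit (reverse orientation) using custom first-strand primers with molecular identifiers for the removal of PCR duplicates, per the labels' protocols. STAR is the only tool named in the submitters' processing notes; its version, the genome build and the annotation are not given in the sources used here. Each deposited file lists transcripts with a length, an effective length, a TPM and an estimated count, per the file headers, a layout that salmon writes. The estimated counts need not be whole and were not normalized. The deposited TPM values divide by effective length, which does not suit reads that come only from the 3' end, and were used only as an alternative for APOC3.

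Each file held 273426 transcripts. Transcript identifiers, without version, were matched to genes of GENCODE 29 (GRCh38), and 201685 (73.76%) matched, holding 94.06% of the estimated counts. Transcripts that did not match were left out of the gene sums, so a gene whose reads lie in newer isoforms is understated. Estimated counts were summed over 57462 genes and rounded to whole numbers. Gene symbols are current ones. Where transcript models overlap or genes have near-identical copies, the estimates may split reads between them. The total per library was 1108120 to 3670120 estimated counts, of which 1041870 to 3470200 lay in matched genes. Counts of replicate libraries differed by more than sampling noise in all 122 pairs (chi-square per degree of freedom 2.36 to 8.53), so none was taken for a copy of another.

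Groups were taken from the labels. Same-labelled libraries were treated as replicates of their dose. The libraries labelled UTC at 0 nM were the controls, and those labelled UTC at 8 nM entered only a check of that label. Each dose was compared with the 12 controls by edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM normalization, its default filter on low counts and a robust quasi-likelihood F test; genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The same test was used for 5000 against 0.00256 nM and for the slope on log10 dose over the 38 ASO#26 libraries. Standard errors were the log2 fold change divided by the square root of F. Levels are CPM with TMM factors over all libraries. Single values were compared by two-sided exact permutation tests. The dose-response curve was a least-squares logistic with the top at 100% and 2000 bootstraps of libraries within dose (Python 3.11.15, scipy 1.17.1). Poisson intervals were exact at 95%.

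In a test on simulated counts with 100 genes changed by 2-fold and 100 by 1.5-fold, the comparison of 4 with 12 libraries recovered 98% and 70% of them over 6203 genes. For 2 against 12 libraries the shares were 90% and 50% over 6112 genes, for 4 against 4 they were 89% and 28% over 6201 genes, and for the dose trend 100% and 65% over 6717 genes. False calls in these 4 tests numbered 14 of 182, 5 of 145, 9 of 126 and 5 of 170 calls. Changed genes were drawn only from those with a mean of at least 10 CPM. Simulated spread followed the expression level alone, without genes of larger spread and without unlike libraries under one label. The real comparisons hold lower genes and such spread as well, so these shares do not give their power.

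Before the data were examined, the groups, tests, alternatives, 29 gene lists and the rule for naming genes were fixed. The rule named APOC3 and its neighbours, and for 5000 nM and the trend the 10 largest rises and 10 largest falls among protein-coding genes past the threshold with a mean of at least 10 CPM, at 5000 nM with every treated library on one side of the control mean. For other comparisons it took up to 5 of each. Up to 4 members with the smallest p were named for each list described, and further called members of lists, IFIT1 and the per-library values of YWHAG were added after the values were seen. Lists were tested by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry. Alternatives were RLE normalization, DESeq2 1.42.0, limma-voom, no filter, one fit of all groups, the replicate number as a block (for doses against UTC together with all groups in one fit; numbers above 2 occur only among the UTC libraries, so that only 2 controls bear on the contrast), each library left out in turn, and subsets of the dose series. For APOC3, log2 of TPM plus 1 was also tested by limma, a scale that understates the change of low values. Alternatives without mitochondrial transcripts, the trend without 1000 and 5000 nM, and the alternatives for single named genes were chosen after seeing the data.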

Results

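The series measured gene expression in primary human hepatocytes, the parenchymal cells of the liver cultured after isolation, 96 h after an oligonucleotide labelled ASO#26 was added to the wells. Its title names APOC3, which encodes apolipoprotein C-III, an inhibitor of lipoprotein lipase carried on triglyceride-rich lipoproteins, and an siRNA against it. Libraries were made from the 3' ends of transcripts with molecular identifiers. Of 52 libraries, 38 were labelled ASO#26 at 10 doses from 0.00256 to 5000 nM in 5-fold steps, with 4 libraries at each dose and 2 at 8 nM. A further 12 were labelled UTC at 0 nM and served as controls, and 2 were labelled UTC at 8 nM, a label that disagrees with itself, and were kept apart. At each dose with 4 libraries the labels rep1 and rep2 each occur on 2 libraries, named here 1a, 2a, 1b and 2b, where the letter only tells libraries of one label apart. Each library held 1108120 to 3670120 estimated counts. Because the labels name no separate donors or experiments, p-values measure the spread between wells or libraries, which may be technical.

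The first question was how far APOC3 mRNA fell with dose. APOC3 (ENSG00000110245) lies on the plus strand of chromosome 11 at 116829706 to 116833072 (GRCh38, GENCODE 29). The controls had 114 ± 9.06 normalized CPM (SD, n = 12). At 0.0128 nM the level was 49.3% ± 10.3 of the control mean (SD, n = 4), at 0.064 nM 29.6% ± 5.42 (n = 4), at 0.32 nM 13.6% ± 4.65 (n = 4) and at 1.6 nM 5.62% ± 2.22 (n = 4). From 8 to 5000 nM it stayed between 1.11% and 5.60% of the control mean. The log2 fold change was -1.02 ± 0.10 (SE) at 0.0128 nM, with an adjusted p of 2.08e-07 from edgeR's quasi-likelihood test, and -4.17 ± 0.15 at 1.6 nM. Of 8 alternatives at 0.0128 nM, 7 kept this call, and the replicate block with all groups in one fit lost it. At the lowest dose, 0.00256 nM, APOC3 was at 85.5% ± 14.5 (SD, n = 4) and was not called by edgeR (log2 fold change -0.21 ± 0.09, adjusted p = 0.9999), while a two-sided exact permutation test of that single gene gave p = 0.0165. All libraries from 0.0128 nM upward lay below the lowest control, and the exact permutation test gave p = 0.000549 at each of these doses with 4 libraries, the smallest it can give (0.000755 after Benjamini-Hochberg adjustment over 11 groups). With 2 libraries the smallest p was 0.011, reached at 8 nM.

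A logistic curve through the 38 libraries, with the top fixed at 100%, had an IC50 of 0.0152 nM (95% bootstrap interval 0.0105 to 0.0205), a Hill slope of 0.776 (0.611 to 1.03) and a bottom of 3.27% (2.11 to 4.56). At 0.0128 nM libraries 1a and 2a were at 38.2% and 43.9%, and 1b and 2b at 61.2% and 54.1%. Over 0.00256 to 1.6 nM APOC3 was not called between libraries deposited first and second under one label (log2 difference 0.16 ± 0.14). At 40 to 5000 nM it was not tested for this, and no curve was fitted by that order. High doses rested on few counts. At 1000 nM the 4 libraries held 2 to 5 APOC3 counts each and 11 together, a pooled level of 1.08% of control with a 95% Poisson interval of 0.539 to 1.93%. At 5000 nM they held 36, or 3.04% (2.13 to 4.21%). These intervals cover counting error only.

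**Figure D1:**
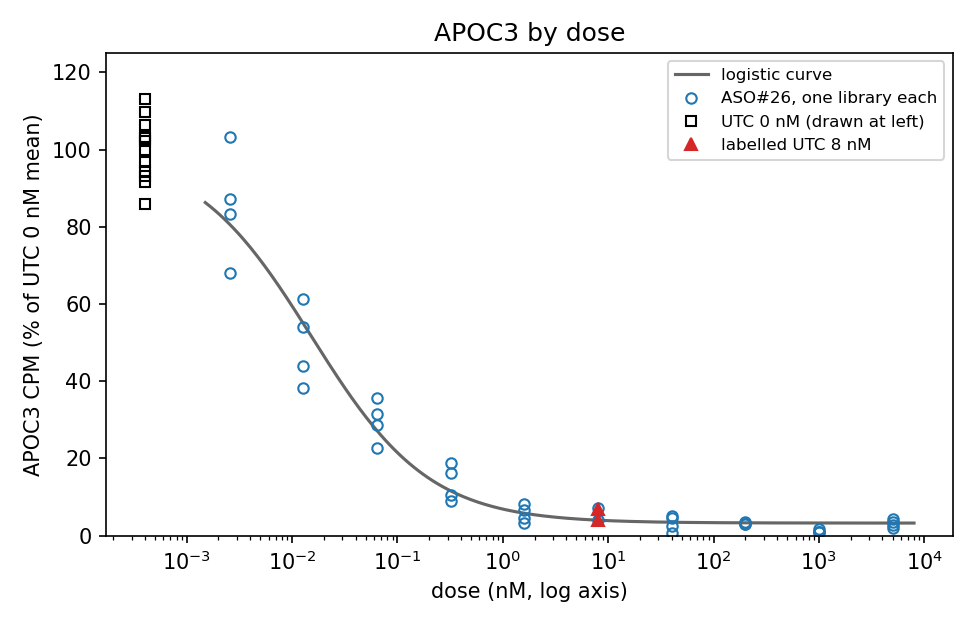
APOC3 CPM of each library as a percentage of the mean of the 12 UTC 0 nM libraries (squares, drawn at the left of the log dose axis), for ASO#26 libraries (circles) and the 2 libraries labelled UTC 8 nM (triangles), with the fitted logistic curve (line, IC50 0.0152 nM). Libraries at 0.0128 nM averaged 49.3% and those at 5000 nM 3.16% of control.

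Neighbours of APOC3 in and around the apolipoprotein cluster were examined beside it. At 5000 nM, APOA1, the main protein of high-density lipoprotein, fell (log2 fold change -0.34 ± 0.08, adjusted p = 0.0082), and the other 6 neighbours tested were not called. These were ZPR1, BUD13, SIDT2, SIK3, PCSK7 and PAFAH1B2. The apolipoprotein genes APOA4 and APOA5 had too few counts to be tested there (means of 0.166 and 3.13 CPM in controls). SIDT2 had -0.57 ± 0.18 (adjusted p = 0.0562). At 1000 nM APOA1 had -0.19 ± 0.08 (adjusted p = 0.446). As a list the neighbours were not called at 5000 nM (camera adjusted p = 0.176), with 1 member lower over all genes and 2 adjusted over the list alone. By dose APOA1 (-0.05 ± 0.01 per 10-fold dose, adjusted p = 0.0299) and SIDT2 (-0.10 ± 0.03, adjusted p = 0.0116) fell. APOA5 had enough counts to be tested by dose and was not called (-0.03 ± 0.06).

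The next question was which other genes differed from the controls at each dose. At 0.0128, 0.064, 0.32 and 1.6 nM, APOC3 was the only gene called by edgeR among 8044 to 8125 tested, and it fell in all 4 libraries of each dose. Without the filter on low counts edgeR called 24, 31, 27 and 4 genes at these doses, and DESeq2 called 2 at 0.0128 nM. At 0.00256 nM edgeR called 0 of 8102 genes, with 342 at an unadjusted p under 0.05, while DESeq2 and limma-voom each called 3.

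From 8 nM, CNOT11 and PHB2 were called lower beside APOC3. CNOT11 is a subunit of the CCR4-NOT deadenylase complex (chromosome 2), and PHB2 is prohibitin 2 of the inner mitochondrial membrane (chromosome 12). Their means were below control before that without a call by edgeR. At 1.6 nM CNOT11 stood at 86.1% (log2 fold change -0.22 ± 0.12) and PHB2 at 74.2% (-0.41 ± 0.10) of the control mean. The dose at which the falls begin is thus not fixed by the calls. CNOT11 was at 80.9 ± 8.06 CPM in controls (SD, n = 12). It reached 59.4% of that mean at 8 nM, 47.4% at 40 nM, 42.4% at 200 nM, 35.9% at 1000 nM and 29.6% at 5000 nM. PHB2 fell from 93.2 ± 9.88 CPM (SD, n = 12) to 51.3% of the mean at 8 nM and 35.7% at 5000 nM. At 8 nM (n = 2), edgeR called 5 genes, all lower: APOC3, PHB2 (log2 fold change -0.97 ± 0.14), GRPEL1, a mitochondrial co-chaperone (-0.85 ± 0.16), CNOT11 (-0.77 ± 0.13) and RRAD, a small GTPase (-0.60 ± 0.10). GRPEL1 was not called at 40 to 5000 nM, where it stood at 90.4% to 115% of control. In one fit of all groups, with or without the replicate block, the count at 8 nM was 1, while DESeq2 called 8. At 40 nM 6 genes were lower (3 in one fit of all groups, with or without the replicate block), the further ones being CNN1, calponin 1 (-0.50 ± 0.09), and the metallothionein MT1F (-0.46 ± 0.09). MT1F belongs to a family of near-identical genes, so its estimate is uncertain.

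**Figure D2:**
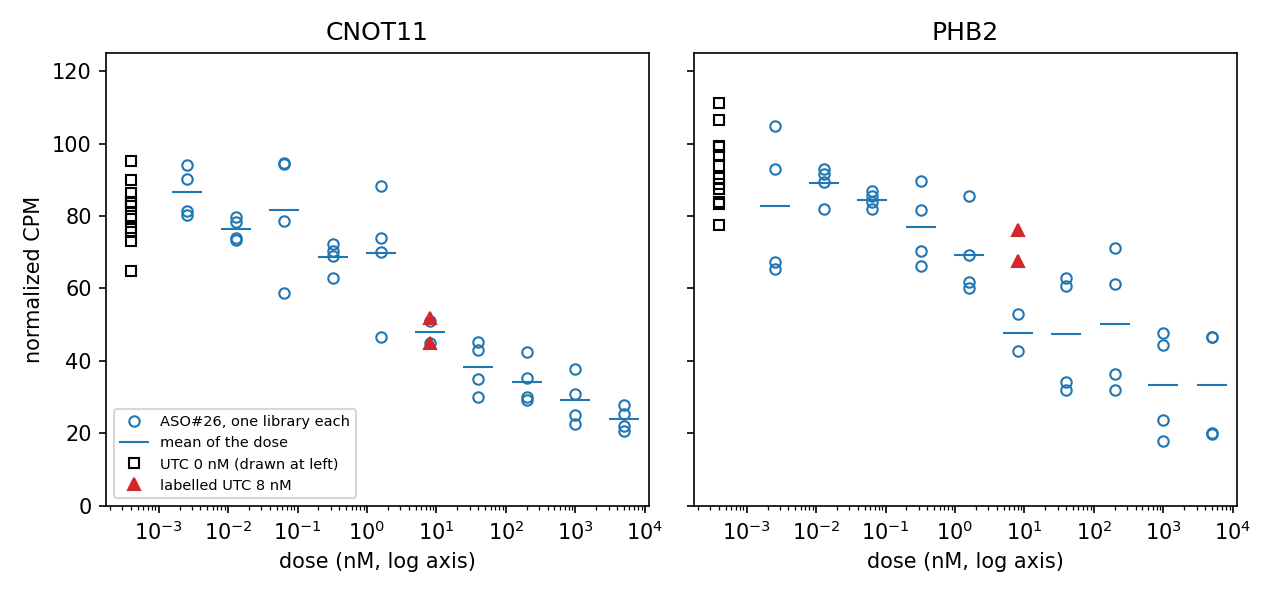
Normalized CPM of CNOT11 (left) and PHB2 (right) in each library against dose on a log axis, with UTC 0 nM libraries as squares at the left, ASO#26 libraries as circles, dose means as bars and the libraries labelled UTC 8 nM as triangles. Control means were 80.9 CPM for CNOT11 and 93.2 CPM for PHB2.

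PHB2 differed between libraries of one dose. At 5000 nM libraries 1a and 2a had 20.2 and 19.7 CPM, while 1b and 2b had 46.6 and 46.6. At 1000 nM the values were 17.9, 23.5, 44.4 and 47.8 in the order 1a, 2a, 1b, 2b. Each lay below the lowest control, 77.6 CPM. Other genes differed between libraries of one label as well. In a comparison chosen after seeing the data, 12 of the 42 genes picked by the naming rule for a rise or fall differed between the libraries deposited first and second under the same label at 40 to 5000 nM: PHB2, YWHAG, NDRG4, SPINK1, SDCBP2, IL11, ODAPH, RRAD, IFI27, MT1F, CNN1 and LMCD1. Among members of the gene lists, PLIN2, LDHA, SQSTM1 and CCNG1 did so too. The mean changes of all of these at such doses thus join unlike libraries.

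At 200 nM, 11 genes were called among 8289, while DESeq2 called 31, one fit of all groups 3 and that fit with the replicate block 2. SPINK1, a trypsin inhibitor (log2 fold change 0.60 ± 0.12), the iron exporter SLC40A1 (0.54 ± 0.11) and the aldo-keto reductase AKR1C1 (0.30 ± 0.06) rose. CNOT11 (-1.25 ± 0.11), PHB2 (-0.89 ± 0.15), CNN1 (-0.56 ± 0.10) and RRAD (-0.52 ± 0.08) were among the 8 that fell. AKR1C1 has close paralogs that share reads. The count was 5 without library 1a and 20 without library 2b.

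At 1000 nM, 47 genes were called among 8364, 22 higher and 25 lower. DESeq2 called 100, and the replicate block with all groups in one fit, which leaves only 2 of the 12 controls to compare with, left 3. Rising genes included the gap junction protein GJB1 (log2 fold change 0.84 ± 0.18), SMC4, a condensin subunit (0.83 ± 0.19), AGMAT (0.55 ± 0.12) and SLC40A1 (0.55 ± 0.10). Among genes with a mean of at least 10 CPM the largest falls after APOC3 were CNOT11 (-1.49 ± 0.12), PHB2 (-1.48 ± 0.18), skeletal muscle actin ACTA1 (-1.45 ± 0.27) and the cytokine IL11 (-1.02 ± 0.23), which ranged from 5.12 to 18.5 CPM between libraries. Mitochondrial transcripts took 44.0% ± 0.577 of counts (SD, n = 4) against 41.0% ± 1.35 in controls (n = 12, two-sided exact permutation p = 0.00907 after adjustment over 33 tests). The count of called genes was 21 without library 1a and 15 without library 2a.

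At 5000 nM, 601 of 8323 genes were called, 289 higher and 312 lower, and 59 of them changed by over 2-fold. These libraries were also deeper, with a mean of 2568970 counts in matched genes against 1845260 in controls. A two-sided exact permutation test of depth gave p = 0.0165, or 0.0907 after adjustment over 33 tests. How far depth added to the number of calls was not tested. The replicate block with all groups in one fit, again with 2 controls in effect, left 81 calls, and one fit without the block 574. Among protein-coding genes with a mean of at least 10 CPM the largest rise was AKR1B1, aldose reductase, from 16.9 ± 5.15 CPM (SD, n = 12) to 84.5 ± 14.7 (SD, n = 4), a log2 fold change of 2.30 ± 0.16 (adjusted p = 2.98e-09). It was not called at 1000 nM (0.31 ± 0.19, adjusted p = 0.686). KRT19, a biliary keratin (1.76 ± 0.21), ODAPH (1.68 ± 0.25), AKR1D1, the 5-beta-reductase of bile acid synthesis (1.56 ± 0.20), and CTAGE4 (1.38 ± 0.37) followed. ZBED10P (1.18 ± 0.16), the chemokine CCL20 (1.15 ± 0.26), INSIG1 (1.03 ± 0.19), the ubiquitin ligase subunit FBXO32 (1.01 ± 0.16) and CPA4 (0.99 ± 0.16) completed the 10 largest rises of such genes. Of these, CPA4, AKR1B1, AKR1D1, CTAGE4, ZBED10P and INSIG1 lie on chromosome 7, between positions 130293134 and 155310235. This was seen after the genes were named, and whether genes of that region moved together was not tested. AKR1D1 and INSIG1 are also counted among members of gene lists below. CTAGE4 belongs to a multigene family and lost its call without library 1a, 2a or 2b, and CCL20 without 1a or 2a.

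Among genes with a mean of at least 10 CPM and POMP aside, falls at 5000 nM were led by APOC3 (-4.94 ± 0.15), CNOT11 (-1.79 ± 0.11), MYL7, an atrial myosin light chain (-1.66 ± 0.24), and PHB2 (-1.54 ± 0.19). The protease ADAMTS15 (-1.53 ± 0.22), the metallothionein MT1H (-1.47 ± 0.19), the actin-bundling protein LCP1 (-1.44 ± 0.23), CNN1 (-1.38 ± 0.21) and RTP3 (-1.27 ± 0.11) followed. ACTA1, below that level on average, had -2.66 ± 0.34. POMP, a proteasome assembly factor, was also called lower, but its size of change is not given: its estimate was 0 in 3 of the 12 controls and up to 94.3 CPM in others, and its call was lost when any 1 of the 4 libraries was left out. The total of called genes was 350 without library 1a and 296 without library 2a.

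**Figure D3:**
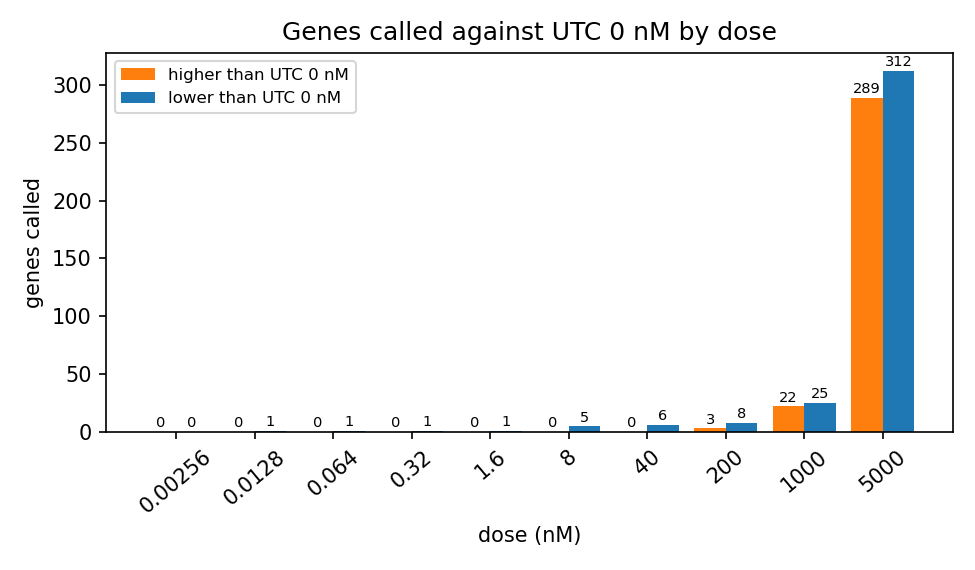
Number of genes called higher (orange) or lower (blue) than the 12 UTC 0 nM libraries by edgeR at each ASO#26 dose. Counts were 1 or fewer up to 1.6 nM and reached 289 higher and 312 lower at 5000 nM. Mean depth also differed, with 1562900 counts in matched genes at 0.00256 nM and 2568970 at 5000 nM.

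Gene groups fixed in advance were then compared at 5000 nM. Genes of cholesterol synthesis rose: 6 of 19 tested were called higher, over all genes and also adjusted over the list alone, and none fell (camera adjusted p = 1.35e-07, and adjusted p = 0.00384 with an estimated correlation). They included HMGCS1, the cytosolic HMG-CoA synthase (log2 fold change 0.91 ± 0.10), INSIG1 and MSMO1 (0.38 ± 0.10). Of 15 fatty acid synthesis genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0266, and adjusted p = 0.127 with an estimated correlation), among them ACLY (0.33 ± 0.08), ELOVL6 (0.48 ± 0.12) and FASN (0.40 ± 0.11), with GPAM lower (-0.28 ± 0.09).

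Mitochondrially encoded genes rose at 5000 nM, with 11 of 15 called higher (12 adjusted over the list alone; camera adjusted p = 9.14e-14, and adjusted p = 0.175 with an estimated correlation). MT-ND6 (0.52 ± 0.06) and MT-CO1 (0.48 ± 0.07) had the smallest p. Their share of counts was 45.1% ± 1.78 (SD, n = 4) against 41.0% ± 1.35 (SD, n = 12; exact permutation p = 0.00604 after adjustment). It was 47.7% and 45.0% in libraries 1a and 2a and 43.7% and 44.2% in 1b and 2b. At 8 of 9 doses, though not at this one, the share was higher in both libraries deposited second. Cytosolic ribosomal protein genes fell, 12 of 42 (20 adjusted over the list alone; camera adjusted p = 1.35e-07, and adjusted p = 0.186 with an estimated correlation), led by RPS3A (-0.38 ± 0.06) and RPL3 (-0.29 ± 0.06). Their share of counts was 10.0% ± 0.716 against 11.9% ± 0.37 (exact permutation p = 0.00604 after adjustment). It was 9.26% and 9.58% in libraries 1a and 2a and 10.8% and 10.3% in 1b and 2b. The mitochondrial and ribosomal shares are parts of one total, so a rise of one lowers the other and their tests are not independent. How much of the ribosomal fall follows from the mitochondrial rise was not tested. In the NF-kB and inflammatory list, 5 of 16 rose and none fell (5 adjusted over the list alone; camera adjusted p = 0.0172, and adjusted p = 0.214 with an estimated correlation): SOD2 (0.58 ± 0.07), CCL20, CXCL1 (0.89 ± 0.21), CXCL6 (0.72 ± 0.17) and BIRC3 (0.27 ± 0.08).

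The other 21 lists tested at 5000 nM were not called as lists. With the replicate block, and thus 2 controls, 3 of them were: interferon-stimulated genes, dedifferentiation and matrix genes (adjusted p = 0.0476) and lysosome and autophagy genes (adjusted p = 0.0476). Among NRF2 targets and metallothioneins, 5 of 21 rose, including AKR1C1 (0.58 ± 0.07) and AKR1B10 (0.46 ± 0.08), and 4 fell, including MT1F (-1.04 ± 0.10) and MT1G (-1.03 ± 0.12); adjusted over the list alone, 5 rose and 5 fell. Of 20 acute phase genes, the fibrinogen chains FGA (0.46 ± 0.10), FGB (0.45 ± 0.07) and FGG (0.56 ± 0.11), with SAA4 and CRP, rose, while HAMP, which encodes hepcidin (-1.21 ± 0.15), and HPX fell, and the counts were the same adjusted over the list alone. Of 24 hepatocyte identity genes, 4 rose, including ALB (0.64 ± 0.08) and GC (0.76 ± 0.10), and 2 fell, TTR (-0.28 ± 0.09) and HPD (-0.44 ± 0.14); adjusted over the list alone, 6 rose and 2 fell. Of 24 dedifferentiation and matrix genes, 5 fell, including THBS1 (-0.97 ± 0.14) and MYL9 (-0.64 ± 0.12), and 2 rose, KRT19 and CD24 (0.45 ± 0.10); adjusted over the list alone, 8 fell and 2 rose. KRT19 and CD24 are also cholangiocyte markers, of which 2 of 7 rose. In the bile acid list AKR1D1, ABCC2 (0.44 ± 0.08) and SLCO1B1 (0.87 ± 0.19) rose and CYP8B1 fell (-1.10 ± 0.28). Among triglyceride and lipoprotein genes APOA2 (0.77 ± 0.10), PLIN2 (0.44 ± 0.09) and APOH (0.52 ± 0.11) rose and ANGPTL4 (-0.40 ± 0.10) and GPAM fell. In the unfolded protein and integrated stress list 4 of 22 fell, among them PSAT1 (-0.54 ± 0.10) and PHGDH (-0.70 ± 0.15), and in the heat shock list CRYAB (-0.94 ± 0.16) and HSPB1 (-0.71 ± 0.17) fell.

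Of 14 interferon-stimulated genes tested at 5000 nM, IFITM2 rose (0.51 ± 0.14) and 13 were not called (camera adjusted p = 0.139, and 0.0173 with the replicate block and thus 2 controls). Between libraries of one label at 40 to 5000 nM, 4 of 17 list members tested, MX1, IFI27, ISG20 and ISG15, named after their values were seen, were lower in those deposited second, and the other 13 were not called. Among p53 targets GDF15 rose (0.33 ± 0.08), and TRIAP1 (-0.41 ± 0.10) and CDKN1A (-0.27 ± 0.08) fell. In the oligonucleotide uptake and silencing list the asialoglycoprotein receptor subunit ASGR1 rose (0.60 ± 0.15) and the other 17 tested were not called. Of 18 PPARA targets, PLIN2 and ACADVL (0.35 ± 0.09) rose and ANGPTL4 fell. In the drug metabolism list UGT2B4, a glucuronosyltransferase, rose (0.57 ± 0.08), and in the cell cycle list CCNB1 rose (0.94 ± 0.25). Among complement and coagulation genes MASP1 rose (0.83 ± 0.25) and prothrombin F2 fell (-0.57 ± 0.08), and among glycolysis and hypoxia genes PKM rose (0.41 ± 0.09) and LDHA fell (-0.29 ± 0.08). The lysosomal HEXA (-0.66 ± 0.17) and the immediate early and stress gene GADD45B (-0.46 ± 0.08) fell as the only called members of their lists, although adjusted over the list alone 3 lysosome and autophagy genes, GLA, LAMP1 and SQSTM1, rose beside the fall of HEXA. Adjusted over the list alone, genes higher and lower numbered 5 and 1 for bile acids, 5 and 3 for triglycerides and lipoproteins, 1 and 4 for unfolded protein and integrated stress, and 1 and 3 for p53 targets. They numbered 4 and 2 for PPARA targets, 1 and 1 for drug metabolism, 1 and 2 for glycolysis and hypoxia, 1 and 1 for oligonucleotide uptake and silencing, and 2 and 1 for cholangiocyte markers. Macrophage marker CD14 rose (0.58 ± 0.13) and the other 3 tested were not called. No endothelial or lymphocyte marker had enough counts to be tested, and 1 stellate cell marker was tested and not called. Median, mean and camera direction differed in sign for triglyceride and lipoprotein genes (median 0.05, mean -0.02, camera up), heat shock genes (0.03, -0.10, down), NRF2 targets and metallothioneins (0.05, -0.05, up), complement and coagulation genes (0.05, -0.00, down) and macrophage markers (-0.08, -0.09, up).

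The 5000 nM libraries were also compared with the 4 at 0.00256 nM, without any UTC library. Of 7860 genes, 79 were higher and 100 lower. AKR1D1 (log2 fold change 2.47 ± 0.28), AKR1B1 (2.41 ± 0.18), ODAPH (1.90 ± 0.36), KRT19 (1.77 ± 0.28) and ZBED10P (1.70 ± 0.21) rose most among genes with a mean of at least 10 CPM. APOC3 (-4.73 ± 0.21), the interferon-inducible IFI27 (-2.55 ± 0.37), CNOT11 (-1.90 ± 0.14), IL17RE (-1.36 ± 0.21) and RTP3 (-1.34 ± 0.17) were lower by most. IFI27 was high and uneven at 0.00256 nM (23.7 ± 11.1 CPM, SD, n = 4, from 11.2 to 35.2). Against the UTC controls it was not called at 5000 nM by edgeR (-0.59 ± 0.48, adjusted p = 0.543). At 0.00256 nM no gene was called against them either, so which of the 2 doses differs from the controls in IFI27 is not settled. The count was 104 and 80 without 5000 nM libraries 1a and 2a, and 112 without 0.00256 nM library 1b. Without the filter on low counts it was higher, as given under the dependence on processing.

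Across all 38 ASO#26 libraries, 482 of 9419 genes had a slope on log10 dose, 244 upward and 238 downward. Mean depth went from 1562900 counts in matched genes at 0.00256 nM to 2568970 at 5000 nM, and the fit held no term for depth. APOC3 had -0.97 ± 0.05 per 10-fold dose (log2 scale). CNOT11 (-0.31 ± 0.02), IFI27 (-0.29 ± 0.09), PHB2 (-0.24 ± 0.03), MYL7 (-0.24 ± 0.03), LMCD1 (-0.17 ± 0.02), ADAMTS15 (-0.17 ± 0.03), NES (-0.17 ± 0.04), CNN1 (-0.17 ± 0.03) and YWHAG (-0.17 ± 0.04) were the next steepest falls among genes with a mean of at least 10 CPM. That of YWHAG lay mostly in libraries 1a and 2a, with 74.6, 66.3, 270 and 254 CPM in 1a, 2a, 1b and 2b at 5000 nM against 253 to 328 in controls. At 1000 nM they had 95.3, 88.5, 250 and 242 CPM, so that 1b and 2b were slightly below the lowest control as well. The steepest rises of such genes were AKR1B1 (0.32 ± 0.06), SDCBP2 (0.21 ± 0.05), the steroid dehydrogenase HSD17B2 (0.21 ± 0.03), CCL20 (0.18 ± 0.04), ZBED10P (0.18 ± 0.04), GC (0.16 ± 0.02), the transporter SLCO1B1 (0.15 ± 0.03), GJB1 (0.15 ± 0.04), NDRG4 (0.15 ± 0.02) and AADAC (0.14 ± 0.02). The top dose carried much of this: without the 5000 nM libraries 102 genes were called, of which 95 were among the 482, and AKR1B1, CCL20, ZBED10P, SLCO1B1, GJB1, AADAC, IFI27 and NES lost their calls. Without the 1000 and 5000 nM libraries, a choice made after seeing the data, 23 genes were called and 22 of them were among the 482.

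By dose, 14 of 27 lists moved. Upward, mitochondrially encoded genes (12 of 15 rose; camera adjusted p = 6.22e-25, and adjusted p = 0.00499 with an estimated correlation), hepatocyte identity (7 of 25, among them GC, ALB and APOH; 7.89e-06 and 0.0122), bile acid genes (6 of 14, led by AKR1D1 with 0.36 ± 0.04; 2.91e-05 and 0.000665) and cholesterol synthesis (4 of 23, led by HMGCS1 with 0.12 ± 0.02; 8.43e-06 and 0.00499) kept their calls with an estimated correlation. So did triglyceride and lipoprotein genes (5 of 31; 0.00726 and 0.0122), fatty acid synthesis (2 of 15; 0.00857 and 0.0412) and cholangiocyte markers (2 of 8, KRT19 and CD24; 0.0173 and 0.0364). Downward, cytosolic ribosomal proteins (9 of 42; 1.54e-08 and 0.0335) and p53 targets (2 of 22, DDB2 and CCNG1, fell and 1 rose; 0.00927 and 0.0412) kept theirs. Adjusted over the list alone, 12 mitochondrial, 8 hepatocyte identity, 8 bile acid and 5 cholesterol genes rose, and 16 ribosomal genes, 1 hepatocyte identity gene and 1 bile acid gene fell. The same counts were 6 and 0 for triglycerides and lipoproteins, 3 and 0 for fatty acid synthesis, 2 and 0 for cholangiocyte markers and 1 and 3 for p53 targets.

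Calls by dose that were lost with an estimated correlation were PPARA targets (6 of 19 rose and 1 fell; adjusted p = 0.0686 with an estimated correlation), acute phase genes (5 of 20 rose; 0.081), interferon-stimulated genes (CXCL10, with -0.58 ± 0.16 at low counts, and IFI27 fell of 25; 0.341), immediate early genes (GADD45B fell of 15; 0.127) and glycolysis and hypoxia genes (LDHA and ADM fell of 14; 0.0637). The other 13 lists were not called.

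The 2 libraries labelled UTC 8 nM were compared with UTC 0 nM as a check of that label. APOC3 was at 5.43% ± 2.11 of the control mean (SD, n = 2), with both libraries below the lowest control (two-sided exact permutation p = 0.011, the smallest possible), and ASO#26 libraries of 8 nM had 5.60% ± 2.32 (n = 2). CNOT11 was lower as well (log2 fold change -0.75 ± 0.13, adjusted p = 0.0134), at 48.4 ± 4.92 CPM. The third gene called was IFIT1, an interferon-induced gene named after its values were seen, at 21.7 ± 2.86 CPM against 2.05 ± 1.15 in controls (log2 fold change 3.40 ± 0.36). PHB2, at 77.1% of the control mean, was not called (-0.38 ± 0.13, adjusted p = 0.893). DESeq2 called 9 genes. No count is given with either library left out, since only 1 would remain and the spread would come from the controls alone.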

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

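The pairing of libraries, the deposit-order term, its depth term and both tests of a batch running through all doses were chosen after the pattern they concern had been seen in single genes. Among 46 sets of 4 libraries examined for a library far from the other 3, 2 stood out, and chance gives about 1 in 20. APOC3 in library 1b at 1000 nM was at 2.08 CPM, against 0.946 to 1.02 in the other 3, on 2 to 5 counts per library. POMP in library 2a at 5000 nM was at 0.617 CPM, with the other 3 at 0. Transcripts that matched no gene in the annotation used, and so entered no comparison, also differed from the controls: 30 at 5000 nM, 2 at 1000 nM and 5 in the libraries labelled UTC 8 nM.

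The low APOC3 of the libraries labelled UTC 8 nM, 5.43% of the UTC 0 nM mean, was weighed against a wrong treatment label. Both libraries lay below the lowest of 12 controls, as a wrong label needs, and a wrong label is a candidate explanation. CNOT11 was lowered as at 8 nM of ASO#26 (48.4 and 48.1 CPM), while PHB2 was higher (67.6 and 76.1 CPM against 42.7 and 52.8) and IFIT1 was called (log2 fold change 3.40) in the UTC 8 nM libraries but not at 8 nM of ASO#26, though PHB2 parts ASO#26 libraries of one label as widely (31.9 and 34.1 against 60.7 and 62.8 at 40 nM), so which treatment a wrong label would hide stays open. Oligonucleotide reaching wells labelled UTC was not tested and stays open, and no biological explanation was tested.

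Libraries with the same dose label fell into pairs in genes such as PHB2 and YWHAG, a 14-3-3 protein. Of the 3 ways to pair the 4 libraries, the leading one called 43 genes at 5000 nM against 11 and 4. Another way led at 1000 nM (45 against 8 and 4) and at 200 nM. At doses up to 1.6 nM the leading way, not always the same, called 7 to 23. The prediction for more than 1 treatment under one label was thus not met, and that explanation cannot be told apart from others. Thinned to equal depth, the same pairing at 5000 nM called 19 genes. Whether these are among the 43 was not checked, so library size stays open for that pairing. Over the 16 libraries of 40 to 5000 nM, a term for the order of deposit within each label called 78 genes, against at most 1 in 39 other assignments. A term for the replicate number called 0. With a term for depth the order of deposit called 92 genes, which argues against library size as the source of the number of calls. Whether the 78 are among the 92 was not checked, so this covers no single gene. Over 77 of the 78 genes the median difference at 0.00256 to 1.6 nM was 6.49% of that at 40 to 5000 nM. This argues against a batch running alike through all doses for those genes, while a batch at high doses only, or a second treatment, may remain. For mitochondrial transcripts a batch running through the doses stays a candidate, since the deposit-order term called 4 genes at 0.00256 to 1.6 nM, MT-CO1, MT-ND5, MT-ND1 and MT-ND4, and the mitochondrial share was higher in both libraries deposited second at 8 of 9 doses, though lower at 5000 nM; no condition was read from the order.

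For POMP, reads shared between transcript models were weighed. The transcript that went most against POMP over the controls (r = -0.842) was no clear partner, since the next candidate had -0.838 and the sum still varied by 26.5 CPM (SD, n = 12). That sum differed by -2.21 on the log2 scale at 5000 nM, more than the 0.5 set beforehand as evidence against shared reads. That the partner was too poor for the test to count was decided after this result was seen, and shared reads are left as not told apart from a fall of POMP.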

How the results depend on the processing

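The alternatives for single named genes, the trend without 1000 and 5000 nM and the fits without mitochondrial transcripts were chosen after seeing the data. APOC3 kept its direction at each dose in each alternative run for it (8 per dose and 6 at 8 nM), with log2 fold changes from -6.77 to -0.12. For APOC3 limma-voom, no filter and one fit without the block were not run at these doses. Its IC50 stayed between 0.0137 and 0.0175 nM. At 0.0128 nM its edgeR call was lost with the replicate block and all groups in one fit together (-1.09, adjusted p = 0.0836). Where a count moved by over 1.5 times, the cause was not tested unless fewer libraries or more genes entered. With no filter on low counts the calls were 29 at 0.00256 nM, 24 at 0.0128, 31 at 0.064, 27 at 0.32, 4 at 1.6, 24 at 8, 17 at 40, 34 at 200, 73 at 1000, 23 in UTC 8 nM and 388 between 5000 and 0.00256 nM. DESeq2 called 3 at 0.00256 nM, 2 at 0.0128, 8 at 8, 31 at 200, 100 at 1000 and 9 in UTC 8 nM, and limma-voom 3 at 0.00256 nM. One fit of all groups called 3 at 0.32 nM, 1 at 8, 3 at 40 and 3 at 200. Deviations of the rep1 libraries, averaged within each group, had no common direction across groups (66 pairs of groups, median r -0.03, range -0.31 to 0.31, 20 over 0.1). That average joins libraries deposited first and second, so pairing by replicate number within either of these was not tested. With the replicate block and all groups in one fit together, which leaves 2 controls in effect, the counts were 0 at 0.0128 nM, 2 at 0.064, 1 at 8, 3 at 40, 2 at 200, 3 at 1000, 81 at 5000. The block alone gave 8 lists at 5000 nM. Leaving out 1 library gave 1 to 2 at 1.6 nM, 1 to 5 at 8, 5 to 20 at 200, 15 to 57 at 1000, 296 to 598 at 5000, 8 to 11 in UTC 8 nM and 80 to 174 between 5000 and 0.00256 nM. The trend called 102 genes without 5000 nM, 23 without 1000 and 5000 nM, 73 in libraries labelled rep1 and 90 in those labelled rep2. Lists at 5000 nM numbered 1 with an estimated correlation and 13 by fry, and lists by dose 9 with an estimated correlation. Of the other values, 175 for main results were the same; for single named genes 187 were the same, 22 lost the call and 0 reversed. Depth limits APOC3 at 1000 nM, where 2 to 5 counts per library were found.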

Other observations

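The tests below were planned before their results were seen, except where said. Further members of lists, picked after their values were seen, also moved by dose. ASGR1 and ASGR2, both subunits of the asialoglycoprotein receptor, rose with dose (0.09 ± 0.02 and 0.07 ± 0.02 per 10-fold dose), while SIDT2 and TSN fell (-0.10 ± 0.03 and -0.06 ± 0.02). AKR1B10 (0.11 ± 0.02) and FTL (0.05 ± 0.01) rose beside AKR1C1. Of the 21 NRF2 targets and metallothioneins tested by dose, 4 rose and 2 fell (5 and 4 adjusted over the list alone). The list was not called (camera adjusted p = 0.089).

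Because CNOT11 and PHB2 fell at doses where few other genes did, sequence shared with the APOC3 mRNA was tested as a hypothesis. The longest stretch CNOT11 shares with the 550-base APOC3 mRNA was 14 bases, above the 95th percentile of 1000 length-matched transcripts (13), and 2.1% of those had as long a stretch. That of PHB2 was 10 bases, with 52.2% as long, over a transcript of 858 bases. Sequence of PHB2 outside that transcript was not searched, so the value covers that transcript alone. The prediction needed both genes, so the test does not decide. The oligonucleotide sequence was not used here.

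Short matches in 3' UTRs were tested over 7667 genes at 5000 nM. Of 15969 words of 7 bases, the one that went with the largest fall is not in the APOC3 mRNA (t = -6.45, with 3 of 200 shuffles as extreme). The first word that is in it ranked 2 (t = -5.53), and 3.26% of the words are in it. The prediction had named the first rank as deciding, but these t values lie too close to exclude such matches, a reading made after the result was seen, so the test leaves them open.

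The spread of APOC3 within a dose exceeded that of every quadruple of controls at 8 of 9 doses. Counting error alone gave an SD of log2 CPM above the control maximum of 0.194 from 0.064 nM upward (0.200 there and 0.469 at 1.6 nM). At 200, 1000 and 5000 nM the observed SD was below the counting SD. At 0.00256 and 0.0128 nM the observed SD (0.247 and 0.304) exceeded both. Low counts and error in the dose added to a well widen the spread, so this test (8 doses) does not decide whether more than 1 treatment stands under one label.

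Other splits of the libraries were tested. As many genes were called by 1 of 40 splits, the real one, at 40 nM (6 genes, highest other 2), 200 nM (11, highest other 2), 1000 nM (47, highest other 3) and 5000 nM (601, highest other 33), by 1 of 35 for 5000 against 0.00256 nM (179, highest other 3) and by 1 of 40 for the trend (482, highest other 3), which argues against chance there. At 0.00256 nM the real count of 0 fixes the outcome, so the splits decide nothing there (40 of 40 called as many, highest other 1). At 0.0128 and 0.32 nM 3 of 40, and at 0.064 and 1.6 nM 4 of 40, called as many as the real 1 (highest other 1 at 0.0128 nM and 2 at the others), so splits alone do not exclude chance for a count as small as 1. For that gene, APOC3, the exact permutation test gave p = 0.000549 at each of these doses, the smallest it can give. That argues against chance there without excluding it, and it takes the libraries as alike apart from dose.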
